A study of Caenorhabditis elegans with 12 samples.

How the data were processed

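Per the labels' protocols, synchronised Caenorhabditis elegans larvae were grown at 20 °C on Escherichia coli OP50 to the L4 stage and then kept for 24 h at 25 °C on OP50 or on Pseudomonas aeruginosa PA14. Total RNA was extracted from whole animals, and 1 µg per sample went into standard Illumina libraries. RNA selection and strand are not given in the sources used here. Per the labels, 12 samples form 4 groups of 3: wild-type N2 on OP50, wild type on PA14, unc-49(e407) on OP50 and unc-49(e407) on PA14. The labels do not say whether the 3 replicates of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

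The authors deposited 1 table of FPKM (read fragments divided by gene length and library size) for 46962 genes in the 12 samples, of which 58 are unannotated loci named by the authors. HISAT2 2.0.4, HTSeq 0.9.1 and DESeq 1.18.0 are listed, with no role or order, per the submitters' processing notes. The genome build is not given in the sources used here. Of the genes, 46817 have an identifier in the WBcel235 annotation, 100% of these overlap it and 69.1% have identical ends. Coordinates are printed as the deposited table gives them.

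In each library 100% of FPKM values multiplied by gene length were whole multiples of a single step, within a tolerance of 0.001 of a read, so whole reads could be recovered. Summed reads were 19035803 to 21088182 per library. The library size behind the deposited FPKM equalled the median-of-ratios size factor times the geometric mean of the summed reads, so the values already carry that scaling. Counting error is small for most genes at this depth, and a gene at 1 FPKM still rests on few reads where it is short. Reads without molecular identifiers are not independent molecules. The exact intervals of read ratios stated here cover counting error only, not the spread between libraries. A floor of 3 reads stands in for a group without reads, with the count of the other group taken as it is. A fold against that floor is therefore not a lower bound, and it does not cover the spread between libraries either. A count test was not run as the main test because the deposited unit is FPKM.

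Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading. Fold changes are on that scale and understate the change of genes with low FPKM. Genes with a mean FPKM of at least 1 over the 12 samples were tested, 11974 in all. The model had 1 mean per group over all 12 samples, no replicate block, and moderated variances with a trend on expression. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. All adjusted p-values for genes and lists come from limma. The comparisons were PA14 against OP50 within each genotype, unc-49 against wild type on each bacterium, and the difference between the infection responses of the genotypes (the interaction). Values of n are 3 per group throughout.

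A set of 41 gene lists was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Families of gene symbols with at least 8 tested members, 133 in all, were tested in the same way. Named genes followed a fixed rule. They are unc-49, the 6 called genes with the largest increase and the 6 with the largest decrease per comparison whose group values did not overlap and whose mean reached 5 FPKM in the higher group, and up to 2 called members per direction of each list described, or the 2 members with the smallest p where no member was called. The lists, the rule, the tests and most alternatives were chosen before the data were examined.

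Alternatives covered the pseudocount (0.1), the filter (none, or a mean FPKM of at least 5), the scaling (TPM, median-of-ratios), sample weights, only the compared groups in the fit, a replicate block, a minimum fold of 2 and each library left out in turn. Another 3 were chosen after seeing the data: voom on the recovered reads, a further filter of 10 reads per library, and scaling by total reads.

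Scripts were tested on simulated data drawn as counts from the wild-type OP50 means and the observed spreads, with changes placed in wild type on PA14, and 11461 genes passed the filter. For infection in wild type, 62.1%, 78.8% and 98.5% of 66 genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 4 false calls. For genotype on PA14 the shares were 65.2%, 84.8% and 98.5%, with 5 false calls. For the interaction they were 28.8%, 63.6% and 93.9%, with 4 false calls. Replicates of a group had Pearson r of 0.980 to 0.989 across genes. Every pair differed by more than sampling noise, with chi-square over degrees of freedom of at least 5.4, so none was treated as a duplicate. That ratio was 27.5, 44.4 and 54.8 for the pairs of wild type on PA14 and at most 12.8 in the other groups. The model shares 1 variance per gene over the 4 groups, so it may understate the spread of wild type on PA14. Genes that share reads with near-identical copies, overlapping genes and antisense genes are uncertain, since the counting rule and strand are not given.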

Results

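Whole-animal RNA-seq profiles were collected from wild-type N2 and unc-49(e407) animals that were moved as L4 larvae to either the laboratory food Escherichia coli OP50 or the pathogen Pseudomonas aeruginosa PA14 for 24 h. UNC-49 is the GABA-A receptor of body wall muscle, and the study asked which genes it regulates with and without the pathogen. Each of the 4 groups had 3 libraries. Summed reads per library ran from 19035803 to 21088182. The first principal component held 59.3% of the variance and separated the bacteria, and the second held 9.2% and separated the genotypes. Wild-type replicate 2 on PA14 stood apart within its group. It had the smallest share of reads from the mitochondrial genome (0.506%) and from ribosomal RNA (0.042%) of the 12 libraries.

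The transcript of unc-49 (chromosome III, 10520676 to 10532705) was present in every library. Its FPKM was 2.74, 2.62 and 2.2 in wild type on OP50, 1.99, 2.76 and 2.08 in wild type on PA14, 2.46, 2.28 and 2.41 in unc-49 on OP50 and 2.26, 2.29 and 2.43 in unc-49 on PA14, from 194 to 271 reads per library. It was not called between the genotypes on OP50 (log2 fold change −0.06, SE 0.12, adjusted p = 0.992) or on PA14 (0.03, SE 0.12, adjusted p = 0.938), nor between PA14 and OP50 in wild type (−0.11, SE 0.12, adjusted p = 0.615) or in unc-49 (−0.02, SE 0.12, adjusted p = 0.936). The level of this transcript therefore does not check the genotype labels.

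To ask what the pathogen changes, animals on PA14 were compared with animals on OP50 within each genotype. In wild type the CUB-domain gene dod-21 rose from 0.103 ± 0.0928 to 159 ± 13.2 FPKM (SD, n = 3), a log2 fold change of 7.18 (SE 0.10, adjusted p = 7.28e-13). B0024.4 rose by 7.49 (SE 0.24), C32H11.9, the CUB-domain gene beside dod-21, by 7.23 (SE 0.11), T24C4.4 by 5.75 (SE 0.20), dct-17 by 5.58 (SE 0.17) and irg-5, an infection response gene, by 5.57 (SE 0.15). In the other direction acdh-1, a short-chain acyl-CoA dehydrogenase of propionate breakdown, dropped from 663 ± 77.4 to 2.00 ± 1.27 FPKM, a log2 fold change of −7.87 (SE 0.26, adjusted p = 1.55e-09). The acyl-CoA synthetase acs-2 fell by 4.87, the cathepsin B-like protease cpr-1 by 4.81, F18E3.12 by 4.28 and the protease cpr-4 by 3.88 on the log2 scale. A further acyl-CoA dehydrogenase, acdh-2, went from 2679 reads over the OP50 group to 2 on PA14, a ratio of 1340 per library size (exact 95% interval 370.6 to 11070).

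All 15 tested genes of the CUB-like list rose in wild type, with a median log2 fold change of 3.33. The same 15 were called when adjusted over the list alone. That list holds chosen genes and not the whole family of CUB-domain genes. Of 14 genes known to depend on the PMK-1 p38 kinase, a central immune kinase, 13 rose and 1 fell (13 and 1 adjusted over the list alone). Among them dod-24 rose by 4.53 and the cation transporter gene catp-3 dropped by 0.90 on the log2 scale. Of 9 genes of the ZIP-2 surveillance pathway, 8 rose (8 adjusted over the list alone), with irg-1 up by 4.82 and irg-3 by 4.46. C-type lectin genes went both ways, with 30 of 71 higher and 17 lower (34 and 18 adjusted over the list alone). In this family clec-4 rose by 5.49 and clec-67 by 4.38, whereas clec-218 fell by 3.70 and clec-5 by 3.22. These 4 lists were called by camera (adjusted p of 2.25e-25, 4.87e-17, 3.60e-10 and 0.000618 in that order), and each had an adjusted p = 0.0405 with an estimated correlation. The CUB-like and PMK-1 lists share members, dod-24 and irg-5 among them, so their calls are not separate evidence.

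Lysozyme genes also split, with 5 of 9 higher and 4 lower (5 and 4 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.353). The antibacterial enzymes lys-2 and lys-1 rose by 3.73 and 2.45, whereas ilys-5 fell by 2.69 and lys-4 by 2.39. Lipase and beta-oxidation genes numbered 7 higher and 6 lower of 25 (7 and 6 adjusted over the list alone) with no call for the list (adjusted p = 0.683). Of these, ech-1.1 and the lysosomal lipase lipl-1 rose by 2.65 and 2.27 beside the lower acdh-1 and acs-2. Of 12 metal and iron genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), with the ferritin ftn-2 up by 0.92 and the zinc transporter cdf-1 up by 0.62, whereas the ferritin ftn-1 fell by 1.7 and the metallothionein mtl-2 went from 231 reads over the group to 1, a ratio of 231.1 (exact 95% interval 41.1 to 9166). That list was not called (adjusted p = 0.511). Intestinal markers numbered 13 higher and 4 lower of 24 (14 and 4 adjusted over the list alone), led by the aspartic protease asp-1 (2.06) and the intermediate filament gene ifd-2 (1.93), with cpr-1 and mtl-2 in the other direction. This list was called (adjusted p = 0.00290) but had an adjusted p = 0.240 with an estimated correlation. Genes first transcribed in embryos were lower for 8 of 13 (10 adjusted over the list alone), with sdz-28 at −1.41 and hch-1 at −1.36. The call of that list (adjusted p = 8.97e-05) was lost at an adjusted p = 0.175 with an estimated correlation.

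**Figure D1:**
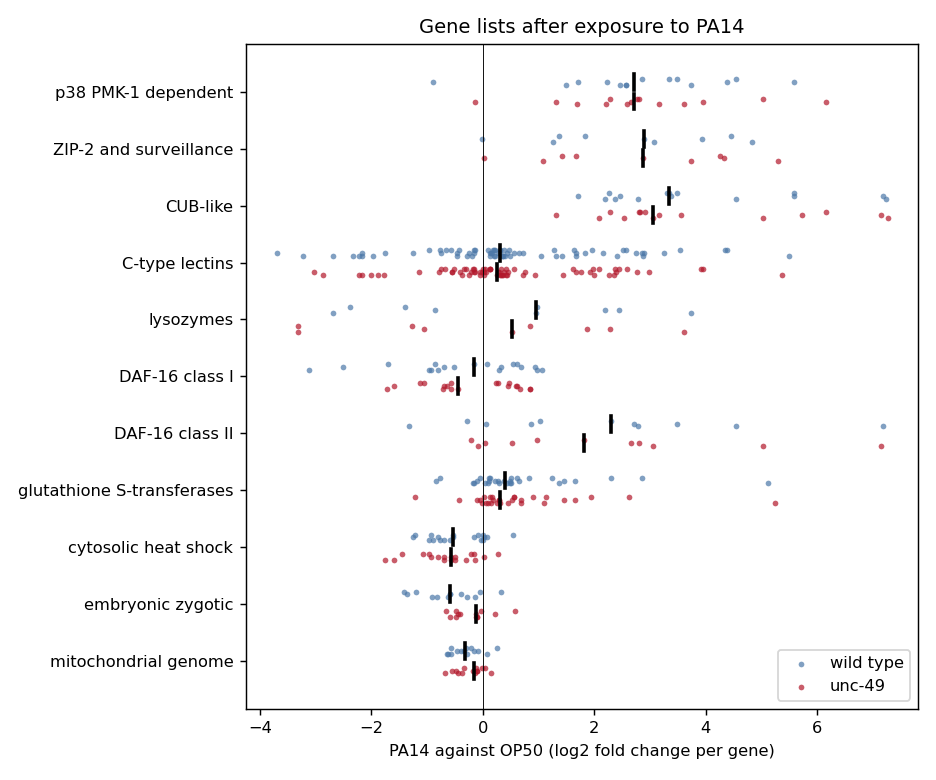
Log2 fold change on PA14 against OP50 of each member gene (points, coloured by genotype) for 11 gene lists, with black bars at the list medians. Members of the CUB-like list all lie above 0 in wild type and in unc-49, with medians of 3.33 and 3.05, whereas C-type lectins and lysozymes spread to both sides.

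In all, limma called 1414 genes higher and 1019 lower on PA14 in wild type, and 582 and 293 changed at least 2-fold. Rescaled to TPM, the split turned to 1145 higher and 1430 lower, so the balance of directions is not fixed by these data. Of the 110 called genes that the naming rule took in this comparison, 90 stayed called whichever library was left out.

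In unc-49 animals the 6 largest increases on PA14 that met the naming rule were of the genes that led in wild type. C32H11.9 rose by 7.26 (SE 0.11, adjusted p = 6.93e-13, n = 3 per group), dod-21 by 7.14 (SE 0.10), B0024.4 by 7.06 (SE 0.24), irg-5 by 6.16 (SE 0.15), T24C4.4 by 5.75 (SE 0.20) and dct-17 by 5.73 (SE 0.17). The largest decreases were those of cpr-1 (−4.69, SE 0.24), acs-2 (−4.15, SE 0.17), cpr-4 (−4.13, SE 0.20), acdh-1 (−4.01, SE 0.26) and E02H4.7 (−3.43, SE 0.13). Reads of acdh-2 went from 1238 over the group to 1, a ratio of 1241 (exact 95% interval 222.3 to 49060). The level of acdh-1 dropped from 670 ± 52.5 to 41.8 ± 13.2 FPKM (SD, n = 3).

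Again all 15 genes of the CUB-like list rose (15 adjusted over the list alone), with a median of 3.05. Of the 14 PMK-1 dependent genes 13 rose (13 adjusted over the list alone), with dod-24 up by 5.03, and of the 9 ZIP-2 pathway genes 8 rose (8 adjusted over the list alone), with irg-1 up by 5.29 and irg-2 by 4.33. These 3 lists had adjusted p = 8.22e-30, 2.88e-21 and 1.99e-12, and each had an adjusted p = 0.0240 with an estimated correlation. C-type lectins numbered 24 higher and 12 lower of 71 (26 and 14 adjusted over the list alone), with clec-4 at 5.37, clec-67 at 3.95, clec-218 at −3.03 and clec-5 at −2.87. Of 11 genes repressed by the insulin-pathway factor DAF-16, called class II, 8 rose (8 adjusted over the list alone). They were led by dod-21 and dod-24, which are also in the CUB-like list. The lectin and class II lists were called (adjusted p of 0.000557 and 3.26e-09) and had an adjusted p = 0.0377 with an estimated correlation. The rise of class II genes was not particular to unc-49, with a median of 1.82 there and 2.29 in wild type. Camera also called that list in wild type whichever library was left out (adjusted p up to 1.20e-06), though not with an estimated correlation.

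Glutathione S-transferases, which conjugate toxic compounds, numbered 12 higher and 1 lower of 30 in unc-49 (12 and 1 adjusted over the list alone). Of these, gst-38 rose by 5.24 and gst-20 by 2.62, and gst-9 dropped by 1.21 on the log2 scale. The list had an adjusted p = 8.57e-07, or an adjusted p = 0.179 with an estimated correlation. Its median was 0.30 in unc-49 and 0.40 in wild type (0.22 without wild-type replicate 2 on PA14). Camera also called it in wild type whichever library was left out (adjusted p up to 0.00142), though not with an estimated correlation. Lysozyme genes numbered 4 higher and 4 lower of 9 (5 and 4 adjusted over the list alone, list adjusted p = 0.574), with lys-2 at 3.60, lys-1 at 2.28, lys-4 at −3.32 and ilys-5 at −3.31. Intestinal markers numbered 13 higher and 4 lower of 24 (14 and 5 adjusted over the list alone), with asp-1 up by 1.90 and ifd-2 by 1.93 and cpr-1 and mtl-2 (−3.40) down. That list was called (adjusted p = 0.00245) with an adjusted p = 0.231 with an estimated correlation. Of 9 tested pals genes, a family of the intracellular pathogen response, 2 rose in unc-49, pals-24 by 2.89 and pals-23 by 2.73, and 3 rose in wild type, where the same 2 genes led at 3.01 and 2.61. Adjusted over the list alone the counts were 2 and 4. The list was called in unc-49 (adjusted p = 0.00720) and wild type (0.0149), with adjusted p = 0.169 and adjusted p = 0.240 with an estimated correlation.

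In unc-49, 1232 genes were higher and 524 lower, with 535 and 128 changed at least 2-fold. The number of lower genes fell to 328 without unc-49 replicate 2 on OP50 and rose to 1102 with sample weights. Of the 95 called genes that the naming rule took here, 69 stayed called whichever library was left out.

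Fold changes of the 11974 tested genes in the genotypes had a Pearson r of 0.85 and a Spearman rho of 0.625 across genes, which are not independent replicates. A total of 1060 genes were higher in both genotypes, against 145.5 for independent lists, and 361 were lower in both, against 44.6. Another 4 genes called in both, asm-3, col-74, T22C8.4 and tts-2, named after their values were seen, were lower in wild type and higher in unc-49. Of 41 lists, camera called 17 in wild type and 15 in unc-49, and 4 and 5 of these held with an estimated correlation. The responses share no library. Without wild-type replicate 2 on PA14 the shared counts were 1084 and 450.

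**Figure D2:**
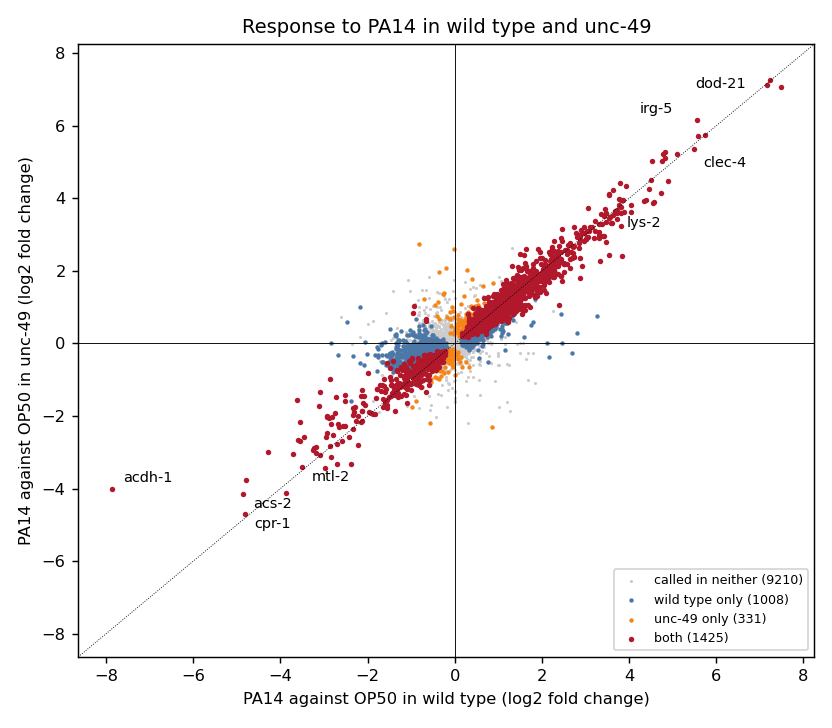
Log2 fold change on PA14 against OP50 in wild type (x axis) and in unc-49 (y axis) for the 11974 tested genes, coloured by whether a gene was called in neither, 1 or both genotypes, with a dotted line of equal change. The gene acdh-1 lies off the line, at −7.87 in wild type and −4.01 in unc-49.

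To ask which genes UNC-49 regulates without the pathogen, unc-49 animals were compared with wild type on OP50, and few genes differed. C07G1.7 (chromosome IV, 8210954 to 8211828) rose from 0.132 ± 0.0428 to 12.4 ± 2.23 FPKM (SD, n = 3), a log2 fold change of 3.55 (SE 0.15, adjusted p = 1.56e-07). The uracil-DNA glycosylase gene ung-1 (chromosome III, 11971461 to 11974092) dropped from 51.4 ± 4.05 to 2.72 ± 0.116 FPKM, a log2 fold change of −3.81 (SE 0.12, adjusted p = 7.18e-09). The short noncoding RNA locus F39E9.17 (chromosome II, 3309988 to 3310006) had 36 reads over the wild-type group and none in unc-49. With unc-49 set to a floor of 3 reads over the group, it was 11.77-fold lower. Also higher were the noncoding RNA F27C1.18 (2.1, SE 0.20), the mitochondrially encoded NADH dehydrogenase subunit nduo-6 (1.86, SE 0.27), the tubulin tbb-6 (1.83, SE 0.12), cex-1 (1.69, SE 0.14) and Y102A5C.36 (1.57, SE 0.17), and F42A10.7 was lower (−2.2, SE 0.23). Small RNA loci with few reads were called as well. Of these, 21ur-14438 had 8 reads over the wild-type group and none in unc-49 (2.62-fold lower against the same floor). For 21ur-9650 the counts were 8 and 1 (ratio 7.85, exact 95% interval 1.05 to 348.1). Whether the reads at F39E9.17 and at such loci came from overlapping transcripts was not tested. The call of 21ur-14438 remained only without wild-type replicate 1 (adjusted p up to 0.147 otherwise) and that of 21ur-9650 only without unc-49 replicate 1 (up to 0.185).

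Of 14 genes of the mitochondrial genome 5 were higher in unc-49 and 1 was lower on OP50 (8 and 1 adjusted over the list alone). The cytochrome oxidase subunit ctc-3 rose by 1.23 (SE 0.18) beside nduo-6, atp-6, ctb-1 and ctc-1 also rose, and the member that fell was the ribosomal RNA MTCE.33 (−1.62, SE 0.28, adjusted p = 0.0115). The list was called (adjusted p = 3.82e-07) but had an adjusted p = 0.447 with an estimated correlation. Reads from the mitochondrial genome made up 1.40 ± 0.102% (SD, n = 3) of unc-49 libraries and 0.764 ± 0.0549% of wild-type libraries on OP50. The mitochondrial chaperone hsp-6, a marker of the mitochondrial unfolded protein response, rose from 301 ± 24.4 to 421 ± 18.2 FPKM (log2 fold change 0.48, SE 0.07, adjusted p = 0.00349). In that list 2 of 14 genes rose, hsp-6 and the protease ymel-1 (0.29), and 5 rose adjusted over the list alone. The list call (adjusted p = 0.00130) was lost at an adjusted p = 0.132 with an estimated correlation. The call of MTCE.33 ended without unc-49 replicate 1 (adjusted p = 0.0549) or 2 (0.0619) or wild-type replicate 3 (0.0599), and that of ymel-1 remained only without wild-type replicate 2 (up to 0.113 otherwise).

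Members of other lists were called singly on OP50, in both directions. The infection response gene irg-4 fell from 7.29 ± 1.36 to 2.82 ± 0.510 FPKM (log2 fold change −1.11, SE 0.14, adjusted p = 0.00206) and was the only called member of the 14 PMK-1 dependent genes (4 lower adjusted over the list alone, list adjusted p = 0.416). The lectin clec-218 was the only called gene of 71 in its family (−0.81, SE 0.11, adjusted p = 0.00244), and 2 were higher and 2 lower adjusted over the list alone (list adjusted p = 0.973). The insulin-like peptide ins-19 dropped from 3.97 ± 0.714 to 0.325 ± 0.347 FPKM (−1.93, SE 0.29, adjusted p = 0.00523) and was the only called gene of 17 in its list (1 lower adjusted over the list alone, list adjusted p = 0.637). Of 9 lysozymes ilys-4 rose (0.95, SE 0.19, adjusted p = 0.0258) and lys-7 fell (−0.58, SE 0.11, adjusted p = 0.0211), with 1 higher and 1 lower adjusted over the list alone and no call for the list (adjusted p = 0.973). The call of ilys-4 remained only without wild-type replicate 1 (adjusted p up to 0.113 otherwise) and that of lys-7 only without unc-49 replicate 1 (up to 0.0992). Of 84 neuropeptide genes nlp-11 was called (0.45, SE 0.10, adjusted p = 0.0458), with 3 higher and 1 lower adjusted over the list alone, and the list had an adjusted p = 0.0141, or an adjusted p = 0.7805 with an estimated correlation. The call of nlp-11 ended whichever library was left out (adjusted p 0.0865 to 0.193), and the list was not called without wild-type replicate 1 (0.0721) or unc-49 replicate 1 (0.147). Among embryonic zygotic genes 2 of 13 fell, sdz-28 (−1.04) and vet-1 (−0.70), and 5 fell adjusted over the list alone. That list was called (adjusted p = 2.36e-07) and lost at an adjusted p = 0.132 with an estimated correlation, and the call of vet-1 remained only without wild-type replicate 1 (adjusted p up to 0.128 otherwise). The sperm calcium channel gene spe-41 rose by 1.13 (SE 0.12, adjusted p = 0.000698) as the only called sperm gene of 24 (1 adjusted over the list alone), and the sperm list was called (adjusted p = 0.000262) with an adjusted p = 0.839 with an estimated correlation.

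Limma called 120 genes higher and 126 lower on OP50, or 215 and 303 with sample weights. Whichever library was left out, 16 of the 32 called genes that the naming rule took here stayed called. The counts fell to 56 and 32 without unc-49 replicate 2, 57 and 40 without unc-49 replicate 3, 66 and 43 without unc-49 replicate 1 and 59 and 36 without wild-type replicate 3, and the count of lower genes fell to 35 without wild-type replicate 2. With no filter the calls of 21ur-14438, 21ur-9650, vet-1, ilys-4, lys-7 and nlp-11 ended (adjusted p 0.0611 to 0.125), as did that of ymel-1 with TPM (0.0890) and that of nlp-11 with voom (0.102). The calls of 21ur-14438 and 21ur-9650 also ended with voom (0.1999 and 0.147) and with a replicate block (0.0663 and 0.0554). That of 21ur-9650 further ended with TPM (0.0600) and a pseudocount of 0.1 (0.167).

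**Figure D3:**
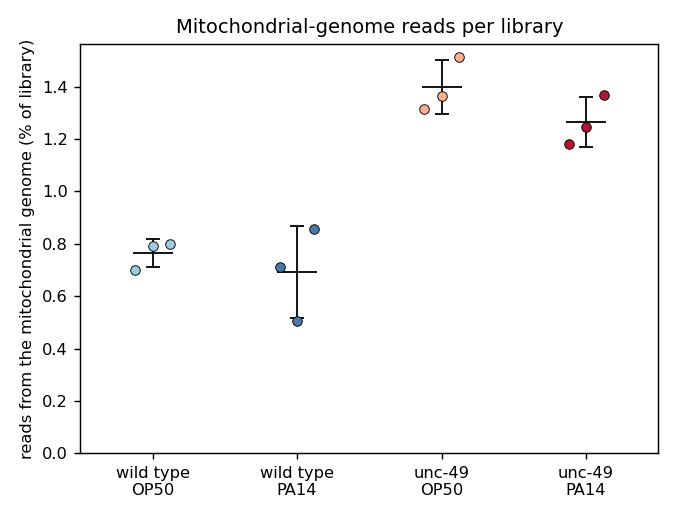
Share of each library's reads that came from the mitochondrial genome (y axis, percent) in the 4 groups, with a point per library, a horizontal line at the group mean and bars of 1 SD (n = 3). The 6 unc-49 libraries lie between 1.179% and 1.512%, above the 6 wild-type libraries at 0.506% to 0.858%.

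The same comparison on PA14 asked which genes UNC-49 regulates under infection, and its leading genes were C07G1.7, ung-1 and F39E9.17, as on OP50, and acdh-1. C07G1.7 rose by 4.03 (SE 0.15, adjusted p = 3.60e-08, n = 3 per group), from 0.105 ± 0.120 to 17.1 ± 2.58 FPKM. The propionate gene acdh-1 was at 41.8 ± 13.2 FPKM in unc-49 and 2.00 ± 1.27 in wild type (log2 fold change 3.88, SE 0.26, adjusted p = 2.51e-05). Also higher were F18E3.11 (1.96, SE 0.33), F27C1.18 (1.80, SE 0.20), nduo-6 (1.69, SE 0.27) and C13A10.2 (1.65, SE 0.19). In the other direction ung-1 dropped by 3.67 on the log2 scale (SE 0.12, adjusted p = 1.10e-08). F39E9.17 had 42 reads over the wild-type group and none in unc-49, which is 13.8-fold lower against a floor of 3 reads. Further decreases were those of the arrestin-domain gene arrd-13 (−1.09, SE 0.09), scl-2 (−1.14, SE 0.16) and the small RNA locus 21ur-15384. The last had 8 reads over the wild-type group and none in unc-49 (2.62-fold lower against the same floor). The call of F18E3.11 ended without unc-49 replicate 2 (adjusted p = 0.0707), and that of 21ur-15384 without unc-49 replicate 1 (0.0639), 2 (0.0721) or 3 (0.0750).

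Genes of the mitochondrial genome were higher for 6 of 14 and lower for 1 on PA14 (8 and 1 adjusted over the list alone), with nduo-6 and nduo-5 (1.62, SE 0.29) leading and MTCE.33 lower (−1.7, SE 0.28). The list was called (adjusted p = 2.26e-08) with an adjusted p = 0.334 with an estimated correlation, and the share of mitochondrial-genome reads was 1.26 ± 0.0965% in unc-49 and 0.692 ± 0.177% in wild type (SD, n = 3). The chaperone hsp-6 rose by 0.49 (SE 0.07, adjusted p = 0.00368) as the 1 called gene of 14 in its list (2 adjusted over the list alone), which had an adjusted p = 0.0221, or an adjusted p = 0.334 with an estimated correlation. Its list was not called without unc-49 replicate 1 (0.0613) or wild-type replicate 1 (0.0754). The call of nduo-5 ended without unc-49 replicate 1 (0.0558), 2 (0.0758) or 3 (0.0956), and that of MTCE.33 without unc-49 replicate 1 (0.0519) or 2 (0.0532).

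Few of the immune genes that rose on PA14 were called between the genotypes. None of the 14 PMK-1 dependent genes was called by limma, 1 higher and 2 lower had an unadjusted p under 0.05, and voom called 1 higher and 1 lower (1 and 1 adjusted over the list alone, list adjusted p = 0.289). The smallest p-values were those of catp-3 (0.78, SE 0.17, adjusted p = 0.0603) and C17H12.8 (−0.67, SE 0.15, adjusted p = 0.0673). None of the 9 ZIP-2 pathway genes was called by limma or voom, and 1 had an unadjusted p under 0.05 (0 adjusted over the list alone, list adjusted p = 0.598), with F11D11.3 (0.71, SE 0.31, adjusted p = 0.331) and irg-3 (−0.29, SE 0.20, adjusted p = 0.540) closest. The lysozyme lys-7, the 1 called gene of 9 in its family, was lower in unc-49, at 62.2 ± 3.72 against 108 ± 16.7 FPKM (log2 fold change −0.78, SE 0.11, adjusted p = 0.00484), and 2 were lower adjusted over the list alone. That list was called (adjusted p = 0.0178) with an adjusted p = 0.334 with an estimated correlation, and was not called without unc-49 replicate 1 (0.0562). Of 71 lectins only clec-45 was called (−1.04, SE 0.18, adjusted p = 0.0156), with 1 higher and 1 lower adjusted over the list alone and no call for the list (adjusted p = 0.259). Its call ended without wild-type replicate 1 (0.0613) or 2 (0.0519).

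Several tissue lists were shifted on PA14 with few or no called members, some higher and some lower. In unc-49 on PA14 the muscle myosin myo-3 (1.46, SE 0.25, adjusted p = 0.0142) and the troponin tni-1 (1.11, SE 0.18, adjusted p = 0.0126) rose among 23 body wall muscle genes (8 adjusted over the list alone), with a list adjusted p = 3.50e-10 and an adjusted p = 0.334 with an estimated correlation. On OP50 myo-3 was called higher as well (1.12). The muscle list was also called there by camera, with a median of 0.18, but not with an estimated correlation. That call was lost without wild-type replicates 1 (adjusted p = 0.187) or 3 (0.107) or unc-49 replicate 1 (0.179) on OP50. Of 24 sperm genes spe-41 was called on PA14 (1.30, SE 0.12, adjusted p = 0.000263) and 6 rose adjusted over the list alone. The sperm median was 1.21 and the list had an adjusted p = 3.50e-10, or an adjusted p = 0.334 with an estimated correlation. Of 83 collagens col-74 was called (1.2, SE 0.25, adjusted p = 0.0435), with 5 higher and 1 lower adjusted over the list alone. The collagen median was 0.65 (0.26 without wild-type replicate 1) and the list had an adjusted p = 1.40e-11, or an adjusted p = 0.334 with an estimated correlation. The glutamic acid decarboxylase unc-25, which makes GABA, rose by 0.64 (SE 0.12, adjusted p = 0.0213) as the 1 called of 7 genes of GABA signalling (2 adjusted over the list alone, list adjusted p = 0.0220, or an adjusted p = 0.334 with an estimated correlation). The calls of myo-3 (0.0721) and tni-1 (0.0645) ended without unc-49 replicate 2, that of tni-1 also without unc-49 replicate 3 (0.0603), that of col-74 remained only without wild-type replicate 1 (adjusted p up to 0.176 otherwise) and that of unc-25 only without wild-type replicate 2 (up to 0.110). The GABA list was not called without unc-49 replicate 1 (0.0613) or wild-type replicates 1 (0.127) or 3 (0.0805).

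Other lists were lower in unc-49 on PA14 with no member called by limma or voom (0 adjusted over the list alone in each). Of 34 genes of germline mitosis and meiosis 12 were lower at an unadjusted p under 0.05 (median −0.12), with glh-4 (−0.27, SE 0.07, adjusted p = 0.109) and glh-2 (−0.24, SE 0.07, adjusted p = 0.137) closest. That list had an adjusted p = 6.29e-06, or an adjusted p = 0.334 with an estimated correlation. Of 33 oocyte and early embryo genes 10 were lower unadjusted (median −0.15), with par-2 (−0.23, SE 0.08, adjusted p = 0.219) and cey-3 (−0.24, SE 0.08, adjusted p = 0.246) closest, and the list had an adjusted p = 1.91e-06, or an adjusted p = 0.360 with an estimated correlation. Of 80 ribosomal protein genes 8 were lower unadjusted (median −0.20, or −0.08 without wild-type replicate 2), with rps-6 (−0.23, SE 0.09, adjusted p = 0.282) and rpl-2 (−0.24, SE 0.10, adjusted p = 0.327) closest, and the list had an adjusted p = 1.47e-09, or an adjusted p = 0.387 with an estimated correlation. Of 21 histone genes 8 were lower unadjusted (median −0.26, or −0.16 without the same library), with his-61 (−0.65, SE 0.19, adjusted p = 0.175) and his-38 (−0.80, SE 0.25, adjusted p = 0.190) closest. The histone list had an adjusted p = 4.68e-05, or an adjusted p = 0.360 with an estimated correlation, and was not called without wild-type replicate 2 (0.126).

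A total of 109 genes were higher and 21 lower in unc-49 on PA14, 29 and 8 with only these groups in the fit and 132 and 26 without wild-type replicate 2. The counts fell to 52 and 9 without unc-49 replicate 2, 55 and 12 without unc-49 replicate 3 and 79 and 11 without unc-49 replicate 1. Whichever library was left out, 12 of the 26 called genes that the naming rule took here stayed called. With only these groups in the fit the calls of F18E3.11, nduo-5, nduo-6, MTCE.33, 21ur-15384, lys-7, clec-45, myo-3, tni-1, col-74 and unc-25 ended (adjusted p 0.0600 to 0.197). The call of col-74 also ended with a replicate block (0.0543) and with no filter (0.126). No filter further ended those of F18E3.11 (0.0550) and 21ur-15384 (0.0602), voom that of 21ur-15384 (0.168) and a pseudocount of 0.1 that of clec-45 (0.205).

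The genotype difference recurred across bacteria at a limited set of genes. A total of 70 genes were higher in unc-49 on both OP50 and PA14, against 1.1 for independent lists (Fisher's exact test, two-sided p = 4.51e-122), and 10 were lower on both, against 0.2 (p = 3.71e-15). Only tts-2, lower on OP50 (−0.65) and higher on PA14 (1.13), was called in opposite directions. Of 41 lists camera called 11 on OP50 and 20 on PA14, and 0 held with an estimated correlation. The comparisons share no library, and genes are not independent replicates. Across the 11974 genes the fold changes had a Pearson r of 0.288 and a Spearman rho of 0.235. Without wild-type replicate 2 on PA14 the shared counts were 78 and 10.

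**Figure D4:**
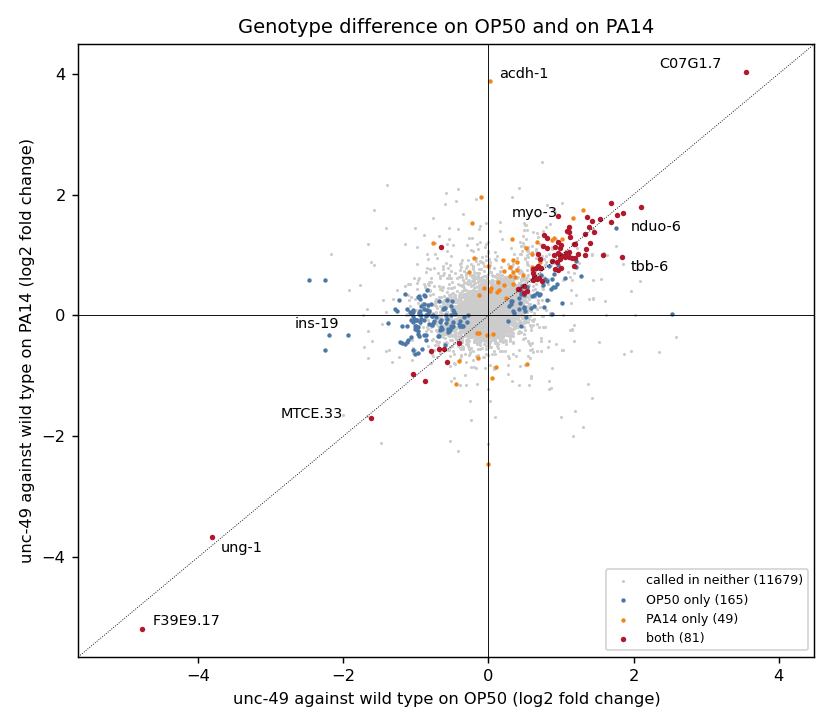
Log2 fold change of unc-49 against wild type on OP50 (x axis) and on PA14 (y axis) for the 11974 tested genes, coloured by whether a gene was called on neither, 1 or both bacteria, with a dotted line of equal change. C07G1.7 at 3.55 and 4.03 and ung-1 at −3.81 and −3.67 lie near that line, and acdh-1 was called on PA14 alone.

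Genes that responded to PA14 in wild type and differed by genotype on PA14 were also compared, since the study asked which response genes UNC-49 regulates. Of the genes called in both, 35 moved in opposite directions and 4 (C10C5.4, lys-7, scrm-4 and Y57G11B.5) in the same direction, or 39 in all. For independent lists 11.76 opposite and 14.66 in the same direction were expected, or 26.4 in all. Both comparisons use the wild-type PA14 libraries, which are too few to split. In 100 simulations with no effect of infection or genotype, 90.7% of genes with an unadjusted p under 0.05 for infection had opposite signs. Here 56.7% of the 1414 genes called higher for infection and 71.5% of the 1019 called lower had opposite signs. Of the genes called in both here 89.7% were opposite. The simulations called a mean of 0 genes in both, so they hold no share to compare with it. Shared libraries push the signs apart, so the opposite direction may come from them, and these simulations cannot decide it. The covariance of the fold changes was −0.0423, against −0.0164 in the simulations, a difference of −0.0259. The correlation was −0.232, against −0.503 in the simulations. The simulations used the same spread per gene in every group, whereas wild type on PA14 had the widest spread between replicates. They may therefore understate the size of the covariance that the shared libraries produce, and no conclusion is drawn from the difference.

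Whether UNC-49 alters the response to the pathogen was tested directly by the difference of responses, which found acdh-1 and the noncoding RNA tts-2. The decrease of acdh-1 was smaller in unc-49 by 3.86 on the log2 scale (SE 0.37, adjusted p = 0.00357, n = 3 per group). On PA14 the libraries held 0.861, 3.37 and 1.77 FPKM of acdh-1 in wild type and 56.98, 34.7 and 33.6 in unc-49. The level of tts-2 was 5.39 ± 1.08 FPKM on OP50 and 2.27 ± 0.313 on PA14 in wild type, and 3.05 ± 0.485 and 6.16 ± 0.561 in unc-49 (interaction 1.78, SE 0.20, adjusted p = 0.0105).

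No gene of the PMK-1 dependent, ZIP-2 pathway or CUB-like lists was called for the interaction by limma over all genes or by voom. At an unadjusted p under 0.05 the first list had 4 higher and 2 lower, the second had 0 and the third had 3 higher and 1 lower. Adjusted over the list alone the counts were 2 higher and 1 lower of 14, 0 of 9, and 1 higher and 1 lower of 15, and the medians were −0.04, 0.04 and 0.15, each turning sign with some library left out (list adjusted p = 0.731, 0.604 and 0.731). The smallest p-values were those of C17H12.8 (−1.05, SE 0.22, adjusted p = 0.241) and irg-4 (0.69, SE 0.20, adjusted p = 0.348), and in the ZIP-2 list those of F11D11.3 (0.67, SE 0.44, adjusted p = 0.826) and irg-1 (0.46, SE 0.32, adjusted p = 0.836).

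Larger shifts were seen in the medians of 13 molting and cuticle genes (1.11) and 83 collagens (0.80, or 0.26 without wild-type replicate 1 on PA14). None was called by limma over all genes or by voom, 8 of the former were higher and 17 of the latter were higher and 1 lower at an unadjusted p under 0.05, and 8 and 4 were higher adjusted over the list alone. Those lists had adjusted p = 8.02e-08 and 9.82e-14, with adjusted p = 0.332 and adjusted p = 0.516 with an estimated correlation. The members with the smallest p were noah-1 (1.37, SE 0.32, adjusted p = 0.282) and cut-2 (1.66, SE 0.45, adjusted p = 0.332), and col-74 (1.97, SE 0.35, adjusted p = 0.150) and col-107 (1.63, SE 0.39, adjusted p = 0.282).

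These 2 genes were the only calls, both higher, against 860 genes at an unadjusted p under 0.05, and voom on the recovered reads called 4 higher and 1 lower. The call of tts-2 ended without wild-type replicate 3 on OP50 (adjusted p = 0.0589), the counts rose to 30 higher and 3 lower without wild-type replicate 2 on PA14 and to 8 higher without wild-type replicate 1 on OP50, and 1 lower gene appeared without wild-type replicate 3 or unc-49 replicate 2 on PA14.

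**Figure D5:**
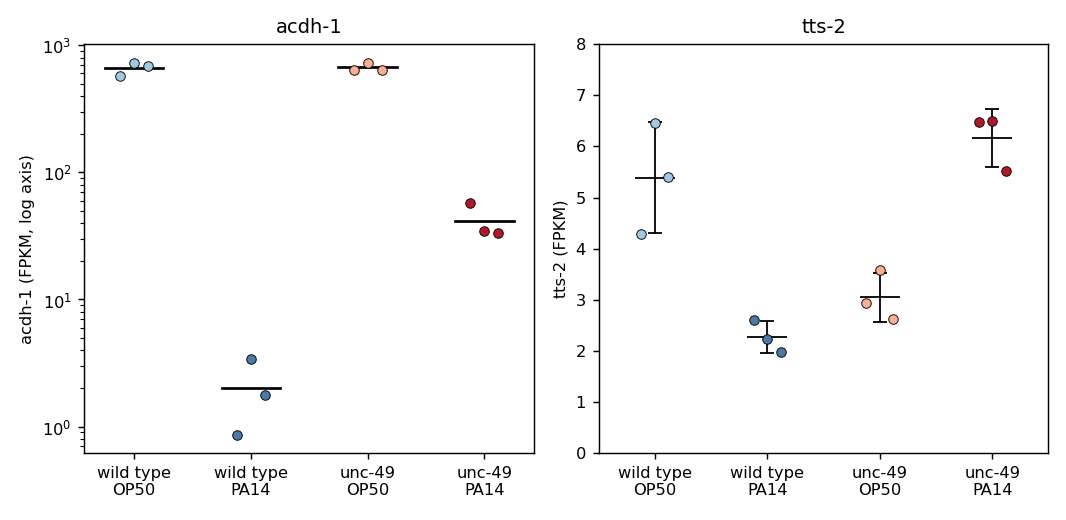
FPKM of acdh-1 (left, log axis, line at the group mean) and tts-2 (right, line at the group mean with bars of 1 SD) in each library of the 4 groups (n = 3). On PA14 the unc-49 libraries hold 33.55 to 56.98 FPKM of acdh-1 and the wild-type libraries 0.8611 to 3.374.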

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

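Among the tests below, the read ratio of acdh-1, the test on the other propionate genes and the count of splits that mix the genotypes were chosen only after the result was seen. What drew attention to each result here is a difference between the genotypes in the response to PA14, tested as the interaction.

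The gene acdh-1 (interaction 3.86, SE 0.37, adjusted p = 0.00357) dropped less on PA14 in unc-49 than in wild type, to 983 to 1632 reads per library against 25 to 99. Few reads do not account for the difference, since the lowest unc-49 library held 9.9 times the reads of the highest wild-type library. A smaller response of the whole propionate breakdown pathway could not be told apart from a change in acdh-1 alone, because the other 4 genes had a median interaction of 0.18 (95% bootstrap interval 0.01 to 0.93). That interval came from resampling genes alone, and the median ran from 0.085 to 0.234 with a library left out. All 4 had a positive interaction, and 1 of them was called when adjusted over the list alone. A hypothesis left open is that loss of UNC-49, or another variant of the strain, may alter how acdh-1 responds to the bacterium. A different intake or growth of PA14 in unc-49 animals was not tested.

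The noncoding RNA tts-2 had an interaction of 1.78 (SE 0.20, adjusted p = 0.0105), lost without wild-type replicate 3 on OP50 (0.0589).

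Of 41 lists, 13 were called for the interaction and 0 with an estimated correlation (smallest adjusted p = 0.332). Median interactions were 1.11 for molting and cuticle genes, 0.80 for collagens (0.26 without wild-type replicate 1 on PA14), 0.75 for adult hypodermis markers (0.44 without the same library), 0.28 for embryonic zygotic genes (0.42 without wild-type replicate 2 on PA14), −0.13 for germline genes and −0.20 for oocyte and early embryo genes. With single libraries left out the medians that follow ran over the ranges given. Sperm genes had a median of 0.58 (0.18 to 0.83), a call lost without unc-49 replicate 2 on OP50 (adjusted p = 0.280) or on PA14 (0.423), wild-type replicate 2 on OP50 (0.467), or wild-type replicates 1 (0.0916) or 3 (0.0981) on PA14. Body wall muscle markers had a median of 0.22 (0.06 to 0.43), lost without wild-type replicate 1 on PA14 (0.604), and ribosomal proteins −0.17 (−0.22 to −0.04), lost without wild-type replicate 2 on PA14 (0.261). Epidermal and other antimicrobial peptides had a median of 0.24 (0.13 to 0.33), lost without unc-49 replicate 2 on OP50 (0.115), wild-type replicate 2 on OP50 (0.0712), unc-49 replicates 1 (0.150) or 2 (0.216) on PA14, or wild-type replicate 3 on PA14 (0.270). Glucuronosyltransferases had a median of 0.06 (0.02 to 0.13), lost without unc-49 replicate 1 on OP50 (0.0968), wild-type replicate 2 on OP50 (0.0529), unc-49 replicate 3 on PA14 (0.147) or wild-type replicate 2 on PA14 (0.518). Lysozymes had a median of −0.20 (−0.30 to −0.13), lost without unc-49 replicate 1 on OP50 (0.0627) or PA14 (0.0543) or wild-type replicate 1 on OP50 (0.0615), and saposin-like genes −0.20 (−0.24 to −0.12), lost without wild-type replicate 1 on OP50 (0.210) or wild-type replicate 2 on PA14 (0.233).

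Splits of the samples do not exclude chance for the count of interaction calls, and they test it weakly. At least the 2 genes of the real split came from 8 of 100 splits, but of these 8 the real one and 4 others kept the genotypes whole on a bacterium and so carry its genotype difference. Among splits that mixed the genotypes on both bacteria 3 of 79 gave as many, at most 4 genes, or 4 of 80 (5%) with the real one. The highest other split called 31 genes, kept the OP50 genotypes whole and put wild-type replicates 2 and 3 and unc-49 replicate 2 on PA14 together, so the genotype structure of the samples enters it, and no other structure was tested. For each of the other comparisons there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes. The real counts and the highest others were 2433 and 1 for infection in wild type, 1756 and 2 in unc-49, 246 and 1 for genotype on OP50 and 130 and 0 on PA14. Every other split mixes the compared groups, so their difference enters the spread and lowers the calls. The interaction splits that mix the genotypes have the same limit.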

How the results depend on the processing

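Voom, the filter of 10 reads and total-read scaling were chosen after seeing the data. The planned median-of-ratios scaling moves almost nothing (127 lower genes for genotype on OP50 against 126), since the deposited values already carry it, so it says nothing about stability. Among calls of named genes 253 remained with a pseudocount of 0.1, 211 with no filter, 248 with TPM, 254 with voom, 254 with sample weights and 256 with a replicate block, and 12, 54, 17, 11, 11 and 9 ended in that order. With only the groups compared 220 remained and 43 ended, and with a 2-fold minimum 170 and 95. Of 76 list calls 9 remained with an estimated correlation and 70 with TPM. With libraries left out, 1311 of 1602 gene results and 462 of 534 list results kept their call. The correlation of replicate numbers after group means ran from −0.147 to 0.222. For 9 of 12 libraries the mean correlation with libraries of other groups was highest at their own of the 3 numbers. A shared structure by replicate number thus remains open, and the main model has no block for it. The replicate block gave 1478 genes higher and 1124 lower for infection in wild type, 1278 and 629 in unc-49, 120 and 124 for genotype on OP50, 31 lower on PA14, and 2 and 0 for the interaction. Genes with few reads limit the small RNA calls.

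For infection in wild type, 582 higher and 293 lower genes changed at least 2-fold, 569 were lower at a mean FPKM of at least 5 and 650 with only these groups. In unc-49 535 and 128 changed at least 2-fold and 1102 were lower with sample weights. On OP50 the genotype counts were 41 and 38 at 2-fold, 71 and 52 at a mean FPKM of at least 5, 215 and 303 with sample weights, and 70 lower with no filter. On PA14 they were 49 and 7 at 2-fold, 63 higher at a mean FPKM of at least 5, and 29 and 8 with only these groups. The interaction had 1 higher at a mean FPKM of at least 5, 5 and 2 with no filter, 4 and 1 with voom, and 1 lower with a pseudocount of 0.1. Stricter filters test fewer genes, and the cause of the other moves was not tested.

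With each library left out, higher and lower counts ran from 56 to 87 and 32 to 160 for genotype on OP50, 52 to 132 and 9 to 26 on PA14, and 1 to 30 and 0 to 3 for the interaction. Infection in unc-49 had 328 to 432 lower. Values that changed sign and were not called were those of ethe-1 on OP50 (−0.22 to 0.007), nduo-5 for the interaction (−0.003 to 0.78), unc-49 on PA14 (−0.031 to 0.132) and, with sample weights, vit-5 for the interaction (−0.009). The ribosomal protein list in wild type turned direction without wild-type replicate 2 on PA14 (adjusted p from 0.00217 to 0.965 over left-out libraries).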

Other observations

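The tests on histone genes and on the overlap of libraries were chosen only after the result was seen. The propionate gene set and the symbol families and genes named here were also picked after their values were seen. The methionine gene set was picked after acdh-1 and hphd-1 were seen to fall, and before the values of its own members were seen.

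Genes of propionate breakdown and of the methionine cycle fell on PA14 in both genotypes. All 5 tested genes of the propionate shunt were lower in each genotype, with medians of −1.61 in wild type and −1.35 in unc-49 (adjusted p = 0.0237 and adjusted p = 0.0213 with an estimated correlation). In wild type hphd-1 fell by 3.59, ech-6 by 1.61, hach-1 by 1.33 and alh-8 by 0.83 on the log2 scale. Of 12 genes of the methionine and S-adenosylmethionine cycle 9 fell in wild type and 11 in unc-49. Camera with an estimated correlation gave adjusted p = 0.0151 and adjusted p = 0.00932 over the same added sets. The synthetase sams-1 was down at −2.13 and −1.86 and metr-1 at −1.46 and −1.46. Both sets are known to be repressed by vitamin B12. A candidate explanation is that PA14 supplies more vitamin B12 than OP50, and the methionine genes, tested as a set that could have stayed level, had a median of −0.67 in wild type (95% bootstrap interval −1.34 to −0.33) and −0.74 in unc-49.

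Called members of F-box gene families mostly went in opposite directions on PA14 in wild type. Of 30 fbxb genes 27 were lower on PA14 in wild type, with a median of −0.92, and 2 in unc-49, with a median of −0.39 (adjusted p = 5.85e-14 and 0.000165, with adjusted p = 0.314 and adjusted p = 0.7345 with an estimated correlation). No fbxb gene was called for the interaction, and unlike counts of calls are not a test of a difference between the genotypes. Of 101 fbxa genes 44 were higher and 2 lower on PA14 in wild type, and 40 higher and 3 lower in unc-49 (adjusted p = 4.68e-07 and 2.13e-07, with adjusted p = 0.314 and adjusted p = 0.283 with an estimated correlation). Of 18 sdz genes, expressed in early embryos, 8 were lower in unc-49 on OP50 (adjusted p = 1.51e-10, with an adjusted p = 0.324 with an estimated correlation).

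The 80 genes called in the same direction between genotypes on both bacteria lay on every chromosome, with 8 on I, 15 on II, 7 on III, 17 on IV, 23 on V, 4 on X and 6 in the mitochondrial genome. Variants linked to unc-49 in the mutant strain that alter genes near them predict an excess near unc-49. Within 2 Mb of it lay 2 of the 80 (2.5%, exact 95% interval 0.3 to 8.7%), obr-1 and ung-1, against 4.9% of the other tested genes (Fisher's exact test, two-sided p = 0.439). This argues against such nearby effects as the cause of most of the 80. A linked variant that alters genes elsewhere was not tested by this window. Few reads do not account for most of the 80 either, since 5 of the 80 (6.2%) had a mean under 20 reads per library. Loss of UNC-49, linked variants that alter genes elsewhere and unlinked variants of the strain all remain open, because the labels name 1 mutant strain.

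Of 14 genes of the mitochondrial genome 5 were higher in unc-49 on OP50 and 6 on PA14, MTCE.33 was lower on both (−1.62 and −1.7), and the list calls were lost at adjusted p = 0.447 and adjusted p = 0.334 with an estimated correlation. More mitochondria per animal would raise nuclear genes of oxidative phosphorylation too, and their median was −0.01 (95% upper bound 0.01 from resampling genes alone) on the bacterium where it was higher and at most 0.04 with a library left out on either, which argues against that. A broader capture of RNAs without long tails could raise histone genes, and their median was −0.09 on OP50 (upper bound −0.05) and −0.26 on PA14. The test was chosen after the result was seen, and RNA selection is not given, so it does not decide the question. A single odd library is excluded, since the lowest unc-49 share of mitochondrial reads was 1.37 times the highest wild-type share. A difference in mitochondrial transcription or RNA stability may remain as a hypothesis, and a batch that follows genotype was not tested.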
